A study of Mus musculus with 6 samples.

How the data were processed

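The samples were 6 mouse libraries of droplet-based 3' single-cell RNA sequencing, with 20000 cells loaded per lane and a stated target of 40000 reads per cell, per the labels. The deposited values are whole-number UMI counts per gene and cell in filtered matrices, without normalization. They were made by the authors with Cell Ranger 7.1.0 on mm10, per the submitters' processing notes; the annotation used there is not given in the sources used here. Groups were taken from the labels: CD45+ tumor, sorted blood neutrophils and sorted tumor neutrophils, with 2 libraries each. Coordinates are 1-based on the mm10 build, from the GENCODE vM21 annotation, which holds all 105 genes looked up. The groups, the designs, the gene and marker lists, the naming rule and most alternatives were fixed before the data were examined.

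Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Scrublet (in scanpy 1.11.5) with its automatic threshold marked between 0 and 0.128% of a library, so after the data were seen the cells with the highest scores were removed instead, up to the rate expected at 0.8% per 1000 cells. This took 677 and 538 cells from the CD45+ libraries, 39 and 145 from blood and 92 and 325 from sorted tumor, and left 8675, 8176, 3076, 5165, 4048 and 6257 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at a resolution of 1.0 followed, with seed 1. A marker counted when it reached 10 CPM and was at least 2-fold above its median over clusters, with a pseudocount of 10 CPM. A cluster was named "-like" when at least 3 markers of a type counted. It stayed unnamed where its leading 10 genes went against the name, where its median UMI count was low and none of those genes was a marker, or where another class's marker score came within a ratio of 0.65 of its own; this last threshold was set after the data were seen. Unnamed clusters held 12.5% and 1.63% of the cells of the CD45+ libraries and 0.228% and 6.16% of those of blood and 0.0988% and 0 of those of sorted tumor. Macrophage-like, monocyte-like and microglia-like clusters were joined as mononuclear phagocytes.

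Neutrophil-like cells numbered 568 and 755 in the CD45+ libraries, 3042 and 4813 in blood and 3639 and 5727 in sorted tumor, with 936883, 1858686, 13094055, 19384783, 14176197 and 22414286 UMIs. Their median depths were 1594, 2445, 4238, 4037, 3754 and 3796 UMIs per cell. Depth therefore limits comparisons that use the CD45+ libraries most. Replicates differed by more than sampling noise (chi-square per degree of freedom 10.6, 10.1 and 20.5), so none was counted as a repeat deposit.

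Cells were not treated as replicates. UMI counts were summed per library over neutrophil-like cells and tested with edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3 and limma 3.58.1. Sorted tumor was compared with blood and with CD45+ tumor libraries with the group as the only term. Tfrc-positive cells (at least 1 UMI) were compared with as many Tfrc-negative cells drawn from 20 bins of total UMIs per library, with the library as a block and Tfrc left out. In the CD45+ libraries neutrophils were compared with mononuclear phagocytes for list genes in no marker list, with the library as a block; leaving out a library there leaves no residual degrees of freedom. Gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation) and fry, adjusted over the lists. With an estimated correlation, camera takes its degrees of freedom from the residuals of the fit, which are few here. Few lists could pass in that setting, so a high adjusted p there does not show that a list result fails. Fry asks whether the genes of a list move on balance in a single direction and does not compare them with other genes. CPM values given beside a fold change use TMM-scaled totals of the same fit, except those of Ngp in CD45+ neutrophils, which come from the fit of sorted against CD45+ cells; CPM given without a fold change use unscaled totals. Values of genes with 0 counts in a group are bounds against 3 counts over the group. Shares of cells carry exact 95% Clopper-Pearson intervals from scipy 1.17.1; UMI shares were computed after thinning each cell to 1000 UMIs with numpy 2.4.6. Plots were drawn with matplotlib 3.10.9.

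The tests were tested on simulated data with 200 genes changed. For tumor against blood, 60% of 2-fold and 93% of 4-fold changes were recovered with 12 false calls (7.27% of calls) over 12878 genes. For the Tfrc sets it was 68% and 92% with 5 false calls (3.03%) over 5876 genes. For sorted against CD45+ libraries it was 21% and 67% with 15 false calls (14.6%) over 11055 genes. The false shares of 7.27% and 14.6% exceeded the level set by the adjusted p threshold. In the real data edgeR called 4103 genes higher and 3920 lower for tumor against blood, and 690 and 516 for the Tfrc sets. Both are far more than the 200 simulated changes, so the simulated rates cannot give the error rates of those comparisons.

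The genes named per comparison were Tfrc, Arg1, Hif1a, Slc2a1, Ldha, Vegfa, Cd274 and Ptgs2. Added to these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 CPM in the higher group, all libraries on the same side, in no other-cell marker list, not mitochondrial, ribosomal, unnamed or antigen receptor genes, and, except for falls against blood, with a CPM in neutrophil-like cells of the CD45+ libraries of at least 0.2 times that in their other cells. The last were the 2 members with the smallest adjusted p of each list. Other members were named as examples of a count or of a sign after their values were seen. No gene was eligible as a largest rise or fall in the comparison of sorted with CD45+ cells. The 18 lists were glycolysis, lactate and pyruvate handling, hypoxia response, iron handling, immunosuppression, histone acylation enzymes, granule proteins, trafficking and maturation receptors, chemokines and cytokines, interferon-stimulated genes, unfolded protein response, antigen presentation, oxidative burst and redox, lipid metabolism, oxidative phosphorylation, proliferation, immediate early and heat shock, and apoptosis and survival. The 17 marker lists were neutrophil, macrophage, monocyte, microglia, dendritic cell, plasmacytoid dendritic cell, T cell, NK cell, B cell, plasma cell, mast cell or basophil, eosinophil, erythroid, platelet, tumour or neural, endothelial, and fibroblast or pericyte. Of 302 listed symbols, 3 were left out, because Mx1 was absent and Aldoa and Ddit3 each belong to more than 1 gene identifier. Ldha is in 2 lists, 3 granule protein genes and 2 trafficking genes are also neutrophil markers, and Siglech is in 2 marker lists.

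Alternatives tried were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom, no low-count filter, a mean CPM of at least 50, a stricter cell filter (500 genes, 5% mitochondrial UMIs), and no doublet removal. Others were leaving out genes over 5 times higher in other cells, each library left out in turn, a fold change of at least 2, sums thinned to equal totals, replicate blocks, all cells without neutrophil selection, the CD45+ libraries added to the fit, at least 2 Tfrc UMIs, no depth matching, cells thinned before summing, sorted or CD45+ libraries alone, another seed, thinning to 500 UMIs, and Leiden resolutions of 0.5 and 1.5. Leaving out the shallow neutrophil cluster of CD45+ tumor replicate 1 and removing the library block within the CD45+ libraries were chosen after seeing the data. Tumor cells and other cells outside the named comparisons were not analysed here.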

Results

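Leukocytes from SB28 brain tumors, a mouse glioma cell line grown in mice, and neutrophils from the blood of tumor-bearing mice were profiled by droplet-based single-cell RNA sequencing on day 18 after 10000 tumor cells had been injected. The 6 libraries formed 3 groups of 2. The first group held all tumor cells that carried CD45, a surface protein of leukocytes. The other groups held neutrophils sorted from blood and from tumor through the same gate, which took CD11b-positive leukocytes with high LY6G and little or no LY6C. The CD45+ tumor libraries contained 9418 and 8851 barcodes with 82077047 and 129422458 unique molecular identifiers (UMIs). The sorted blood libraries contained 3121 and 5330 barcodes with 13945799 and 21636838 UMIs, and the sorted tumor libraries 4158 and 6612 barcodes with 21841452 and 32628481 UMIs. The labels number the samples but do not say that they came from separate mice, so p-values here measure only the spread between these samples, which may be technical. Intervals and floors cover counting error only.

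Neutrophil-like cells made up 96.0% ± 4.04 (SD, n = 2) of the cells in the sorted blood libraries, 90.7% ± 1.16 in the sorted tumor libraries and 7.89% ± 1.90 in the CD45+ tumor libraries. In single CD45+ libraries the share was 6.55% (95% Clopper-Pearson interval 6.04 to 7.09) and 9.23% (8.62 to 9.88). Most CD45+ tumor leukocytes were mononuclear phagocyte-like, a class that joins macrophage-like, monocyte-like and microglia-like cells, at 70.8% ± 6.88. The sorted tumor libraries still held 8.84% ± 0.91 of such cells, and the sorted blood libraries 0.084% ± 0.065. In the CD45+ libraries dendritic cell-like cells took 9.32% ± 1.10, T or NK cell-like cells 2.98% ± 0.958, B or plasma cell-like cells 1.56% ± 1.35, mast cell or basophil-like cells 0.213% ± 0.008 and stromal or tumour cell-like cells 0.151% ± 0.132. Clusters without a name took 7.07% ± 7.69 of the CD45+ libraries, 3.19% ± 4.19 of the blood libraries and 0.049% ± 0.07 of the sorted tumor libraries. The sort gates set most of these shares, and no test was run on them.

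**Figure D1:**
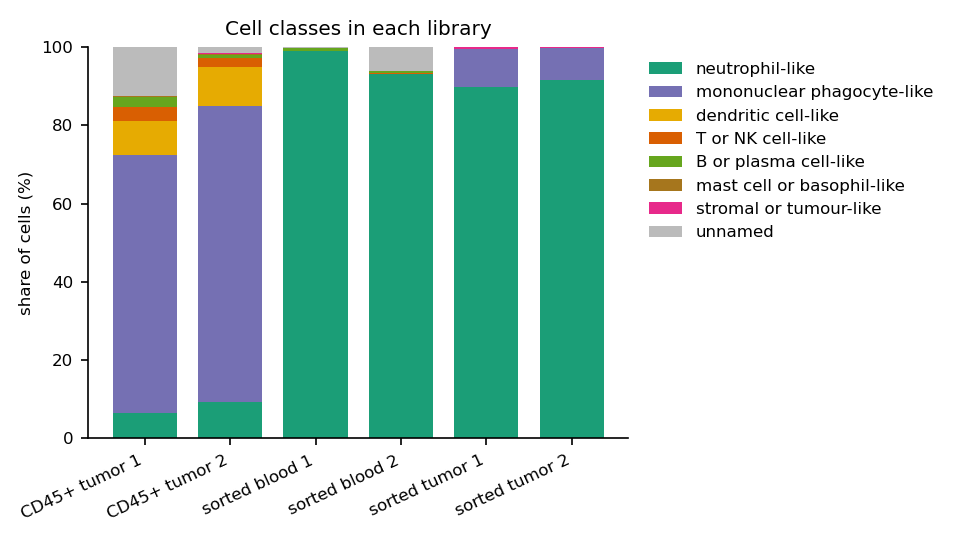
Share of cells (%) in each cell class, stacked, for each of the 6 libraries. Neutrophil-like cells fill most of the sorted blood and sorted tumor bars, and mononuclear phagocyte-like cells most of the CD45+ tumor bars (70.8% ± 6.88, n = 2).

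The same gate in both tissues allowed neutrophils inside the tumor to be compared with those still in the circulation. Any difference in how tumor and blood were handled before the sort goes with the tissue, so handling and tissue cannot be told apart. All 8 genes chosen by name in advance were higher in tumor neutrophil-like cells, though for Arg1 the source of the RNA is open. Tfrc, which encodes the transferrin receptor CD71, rose by 3.64 ± 0.16 on the log2 scale (SE), from 4.84 ± 0.17 CPM (UMI counts scaled to library size, SD, n = 2) in blood to 60.3 ± 9.04 in tumor. Values after gene names below are log2 changes ± SE unless a unit is given. Cd274, which encodes the checkpoint ligand PD-L1, rose by 4.70 ± 0.16 (768 ± 3.54 against 29.4 ± 4.92 CPM), and Ptgs2, which encodes the prostaglandin synthase COX-2, by 3.61 ± 0.14 (2130 ± 40.9 against 175 ± 17.8 CPM). The glucose transporter gene Slc2a1 rose by 2.82 ± 0.14 (643 ± 35.2 against 91.4 ± 13.7 CPM). The lactate dehydrogenase gene Ldha rose by 2.68 ± 0.15 (750 ± 136 against 117 ± 2.94 CPM) and the angiogenic factor gene Vegfa by 3.28 ± 0.17 (191 ± 41.0 against 19.7 ± 0.21 CPM). Hif1a, which encodes the oxygen-regulated transcription factor subunit HIF-1α, rose less, by 1.37 ± 0.15 (451 ± 67.9 against 175 ± 23.0 CPM). The arginase gene Arg1 had 0 counts in blood neutrophils and 215 in tumor neutrophils, which is at least 63.6-fold higher against a floor of 3 counts over the group, at 6.44 ± 0.59 CPM in tumor. Phagocyte RNA could account for this level. Arg1 was at 0.641% and 0.619% of its level in phagocyte-like cells of the same libraries. The median for macrophage markers was higher, at 2.92% and 1.87%.

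Adjusted p in edgeR's quasi-likelihood test was 1.2e-06 for Tfrc, 3.72e-07 for Cd274, 6.83e-07 for Ptgs2, 1.92e-06 for Slc2a1, 3.21e-06 for Ldha, 2.06e-06 for Vegfa, 9.33e-05 for Hif1a and 1.75e-05 for Arg1. On the mm10 build, Tfrc (ENSMUSG00000022797) lies on chromosome 16 at 32608920 to 32632794 on the plus strand. Cd274 (ENSMUSG00000016496) lies on chromosome 19 at 29367455 to 29388095 on the plus strand, and Slc2a1 (ENSMUSG00000028645) on chromosome 4 at 119108711 to 119137983 on the plus strand. Arg1 (ENSMUSG00000019987) lies on chromosome 10 at 24915221 to 24927484 on the minus strand. All 4 are annotated as protein-coding genes, and the counts are per gene, so that no value belongs to a single exon.

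The largest rises that met the naming rule were those of the interleukin gene Il1a (11.49 ± 0.31, 346 ± 57.2 against 0.13 ± 0.11 CPM) and the neutrophil-attracting chemokine genes Cxcl3 (10.47 ± 0.35, 10323 ± 3452 against 7.22 ± 1.24 CPM) and Cxcl1 (9.01 ± 0.21, 90.5 ± 4.603 against 0.165 ± 0.035 CPM). The others were those of the ATP-gated channel gene P2rx7 (9.31 ± 0.38, 147 ± 42.0 against 0.2 ± 0.18 CPM), Rab15 (9.09 ± 0.46) and the carbonic anhydrase gene Car2. Car2 had 2 counts in blood and 2020 in tumor, a ratio of 897 with a 95% counting interval of 248 to 7408. The largest falls were those of Asb7 (−3.64 ± 0.16), the DNA repair gene Xpc (−3.49 ± 0.13), Tspan2 (−3.40 ± 0.16) and Hacd4 (−3.32 ± 0.14). The ubiquitin ligase gene March1 (−3.29 ± 0.12, 33.5 ± 1.58 against 326 ± 23.3 CPM) and the integrin gene Itga4 (−3.27 ± 0.15, 45.8 ± 8.97 against 440 ± 4.41 CPM) came next. The naming rule required all 12 to lie on the same side in both tumor libraries relative to both blood libraries.

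Markers of other cells moved with the tumor. Of 10 measured macrophage markers 8 rose and 1, Csf1r, fell (median log2 change 7.03, or 6.28 with genes near the floor set to their bound, camera adjusted p = 1.96e-09, adjusted p = 0.325 with an estimated correlation). The complement gene C1qa stood at 104 ± 9.60 CPM in tumor neutrophil-like cells against 2 counts in blood, a ratio of 1503 (95% counting interval 416 to 12417). Monocyte markers (5 of 7 rose, 0 fell), microglia markers (8 of 9 rose, 1 fell) and plasmacytoid dendritic cell markers (4 of 4 rose) each had a camera adjusted p of 0.0523. Pecam1, the measured endothelial marker, rose by 2.77, and Col1a1, the measured fibroblast or pericyte marker, by 4.30. All 4 measured erythroid markers fell (median −4.99, camera adjusted p = 0.483). Neutrophil markers fell in 7 and rose in 3 of 11 (median −0.77, camera adjusted p = 0.483). Ly6g was at −1.83 and G0s2 at 4.29. Dendritic cell markers (1 of 4 rose, 2 fell), platelet markers (1 of 3 rose, 1 fell), B cell markers (0 of 3 rose, 1 fell) and T cell markers (2 of 4 rose, 2 fell) were not called by camera or fry, and of 2 measured eosinophil markers 0 changed. For T cell markers the median (2.34) and mean (2.66) were positive while the camera direction was down, and for platelet markers the median was 0.09 and the direction down. No NK cell, plasma cell, mast cell or basophil, or tumour or neural marker passed the expression filter. To show how far each gene below is shared with other cells, its CPM in neutrophil-like cells is given as a ratio to that in all other cells of the CD45+ tumor libraries.

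Among glycolysis genes 15 of 18 measured rose and 3 fell (median log2 change 1.88, camera adjusted p = 8.11e-09, adjusted p = 0.399 with an estimated correlation). The hexokinase gene Hk2 rose by 3.81 ± 0.13 (514 ± 3.33 against 36.8 ± 4.09 CPM, ratio to other cells 1.84) and Pfkp by 3.24 ± 0.12 (ratio 2.05), while Pfkfb4, Gpi1 and Slc2a3 fell by 1.85, 0.84 and 0.39. Of the genes of lactate and pyruvate handling, 7 of 10 rose and 3 fell (median 1.96, camera adjusted p = 0.0152, adjusted p = 0.399 with an estimated correlation). The pyruvate dehydrogenase kinase gene Pdk1 was at 3.47 ± 0.18 (ratio 0.916). Hypoxia response genes rose in 17 of 19 and fell in 1, Mxi1 (median 3.81, camera adjusted p = 2.75e-22, adjusted p = 0.19 with an estimated correlation). Ero1l, which encodes an oxidase of protein folding, rose by 5.83 ± 0.14 (832 ± 68.0 against 14.7 ± 0.66 CPM, ratio 4.802), and the prolyl hydroxylase gene Egln3 by 4.93 ± 0.13 (ratio 8.38). Vegfa had a ratio of 0.418. Of iron handling genes 8 of 12 rose and 3 fell (median 1.11, camera adjusted p = 0.0387, adjusted p = 0.415 with an estimated correlation). The heme oxygenase gene Hmox1 rose by 2.78 ± 0.15 (ratio 0.875), and Slc40a1, which encodes the iron exporter ferroportin, fell by 1.93 ± 0.11.

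Chemokine and cytokine genes rose in 15 of 16 with 0 falls (median 5.63, camera adjusted p = 7.15e-29, adjusted p = 0.119 with an estimated correlation), and Ccl4 by 8.15 ± 0.21 (7831 ± 1035 against 27.6 ± 2.71 CPM, ratio 10.8). Immunosuppression genes rose in 15 of 18 and fell in 1 (median 3.42, camera adjusted p = 1.33e-15, adjusted p = 0.19 with an estimated correlation). The interleukin-1 receptor antagonist gene Il1rn rose by 3.90 ± 0.13 (ratio 8.03), while Arg1 had a ratio of 0.036. Interferon-stimulated genes rose in 16 of 23 and fell in 1 (median 0.96, camera adjusted p = 0.00358, adjusted p = 0.512 with an estimated correlation), among them Isg15 (2.70 ± 0.17, ratio 2.93) and Bst2 (2.94 ± 0.19, ratio 0.132). All 8 measured antigen presentation genes rose (median 2.88, camera adjusted p = 0.000147, adjusted p = 0.19 with an estimated correlation). The costimulatory gene Cd80 was at 2.28 ± 0.11 (ratio 2.40) and the MHC class II gene H2-Eb1 at 4.49 ± 0.27 (ratio 0.054). The H2-Eb1 change was −0.89 when all cells of each library were summed without selecting neutrophil-like cells.

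Unfolded protein response genes rose in 12 of 16 and fell in 3 (median 1.72, camera adjusted p = 7.45e-06, adjusted p = 0.19 with an estimated correlation). Ppp1r15a was at 3.33 ± 0.13 and the chaperone gene Hsp90b1 at 2.26 ± 0.11. Immediate early and heat shock genes rose in 12 of 17 and fell in 1 (median 1.14, camera adjusted p = 1.6e-08, adjusted p = 0.192 with an estimated correlation). Jun was at 3.45 ± 0.12 and Hsp90aa1 at 3.31 ± 0.13. Apoptosis and survival genes rose in 11 of 14 and fell in 2 (median 2.19, camera adjusted p = 2.19e-09, adjusted p = 0.19 with an estimated correlation). The survival gene Bcl2a1b was at 5.18 ± 0.15 and Gadd45b at 3.69 ± 0.12. Oxidative burst and redox genes rose in 6 and fell in 6 of 16 (median 0.33, camera adjusted p = 0.0473, adjusted p = 0.399 with an estimated correlation). The superoxide dismutase gene Sod2 was at 4.16 ± 0.15 and the thioredoxin reductase gene Txnrd1 at 3.30 ± 0.12.

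Camera called none of the remaining 6 lists, of which fry called lipid metabolism (adjusted p = 0.033). Histone acylation enzymes rose in 5 and fell in 6 of 15 (median −0.15, camera adjusted p = 0.479). The acetyltransferase gene Kat2b was at −1.97 ± 0.12 and the alanyl-tRNA synthetase gene Aars at 2.65 ± 0.21. Granule proteins rose in 3 and fell in 7 of 14 (median −0.82, camera adjusted p = 0.371). Hp, which encodes haptoglobin, was at −1.48 ± 0.15 and Cd177 at 1.84 ± 0.20. Trafficking and maturation receptors rose in 7 and fell in 7 of 15 (median 0.18, mean −0.06 and direction down, camera adjusted p = 0.479). The adhesion molecule gene Icam1 was at 4.47 ± 0.19 and the selectin ligand gene Selplg at −1.69 ± 0.12. Lipid metabolism genes rose in 11 and fell in 4 of 16 (median 1.5, camera adjusted p = 0.0626). The cholesterol exporter gene Abca1 was at 2.95 ± 0.14 and Dgat1 at 2.23 ± 0.13. Oxidative phosphorylation genes rose in 3 and fell in 9 of 24 (median −0.24, mean 0.03 and direction down, camera adjusted p = 0.479). The cytochrome c gene Cycs was at 2.76 ± 0.14 and Ndufs1 at −1.28 ± 0.16. Proliferation genes rose in 6 and fell in 2 of 15 (median 0.39, camera adjusted p = 0.479). Pcna was at 1.96 ± 0.15 and Hmgb2 at −1.02 ± 0.14.

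In all, edgeR called 4103 genes higher and 3920 lower in tumor among 12878 tested at a Benjamini-Hochberg adjusted p under 0.05, and 3028 and 2230 of these differed at least 2-fold. Adjusted over the list alone, the counts were the same in 16 of the 18 lists; chemokines and cytokines had 1 fall more and proliferation genes 1 fewer. With an estimated correlation camera called 0 of the 18 lists (4 at an unadjusted p under 0.05), and fry called 13. The loss of calls is not due to correlation alone. For chemokines and cytokines the estimated correlation was −0.00407, below the preset 0.01. Their unadjusted camera p still went from 3.97e-30 to 0.00659, as few residual degrees of freedom remain. Blood and tumor neutrophil-like cells lay in different clusters, mainly 0, 8 and 17 in blood and 1, 2, 6, 13 and 14 in tumor, so the class was compared across clusters of the same name.

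**Figure D2:**
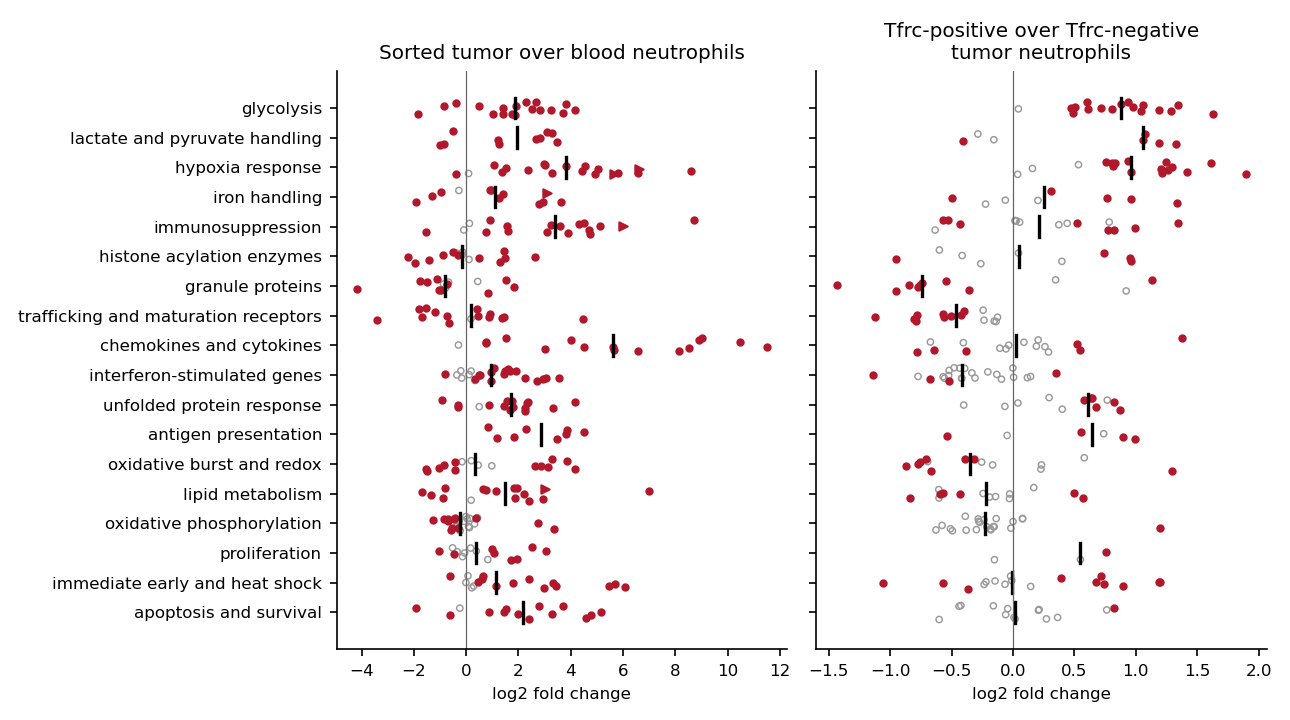
Log2 fold change (horizontal axis) of each measured gene in the 18 fixed lists (vertical axis), for sorted tumor over blood neutrophils (left) and Tfrc-positive over Tfrc-negative tumor neutrophils (right). Filled points passed an adjusted p of 0.05, triangles are genes with 0 to 3 counts in blood drawn at their floor bound, and black bars are list medians, which reach 5.63 for chemokines and cytokines on the left and 0.96 for the hypoxia response on the right.

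The share of neutrophil-like cells with a UMI of a gene was compared after thinning each cell to 1000 UMIs. This left out 143 and 361 shallower blood cells, 147 and 204 sorted tumor cells, and 67 and 53 cells of the CD45+ tumor libraries. Tfrc was seen in 4.69% ± 0.51 (SD, n = 2) of sorted tumor neutrophils, 0.414% ± 0.049 of blood neutrophils and 4.12% ± 0.39 of CD45+ tumor neutrophils; unthinned shares were 12.7%, 1.92% and 7.83%. In the CD45+ libraries the Tfrc share was 3.21% (95% Clopper-Pearson interval 1.55 to 5.82) and 1.604% (0.332 to 4.62) in T or NK cell-like cells. It was 4.55% and 6.12% in B or plasma cell-like cells, and 1.013% and 1.13% in mononuclear phagocyte-like cells. The CD45+ neutrophil share of Tfrc therefore stood above that of phagocytes, but not above that of B or plasma cell-like cells, and its intervals (2.77 to 6.57 and 2.55 to 5.55) overlapped those of T or NK cell-like cells. Median depth before thinning was 3817 and 3849 UMIs in sorted tumor neutrophils and 4307 and 4143 in blood neutrophils. It was 1674 and 2516 in CD45+ tumor neutrophils, 3422 and 5473 in T or NK cell-like cells and 8095 and 13190 in phagocyte-like cells.

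Cd274 was seen in 32.0% ± 0.30 of sorted tumor, 3.19% ± 0.32 of blood and 31.0% ± 1.74 of CD45+ tumor neutrophils (unthinned 50.8%, 8.57% and 39.3%). It was seen in 11.2% and 6.95% of T or NK cell-like cells, 13.1% and 12.2% of B or plasma cell-like cells and 14.4% and 11.04% of phagocyte-like cells. Vegfa was seen in 11.4% ± 2.73, 2.38% ± 0.29 and 10.4% ± 2.81 (unthinned 24.2%, 7.08% and 15.96%). The share was 7.69% and 6.95% of T or NK cell-like and 26.1% and 29.1% of phagocyte-like cells, and the intervals of Vegfa in CD45+ neutrophils (9.62 to 15.6 and 6.46 to 10.7) and T or NK cell-like cells (4.99 to 11.2 and 3.75 to 11.6) overlapped. In B or plasma cell-like cells Vegfa was seen in 0.505% (0.0128 to 2.78) of 198 cells and in 0 of 49 (upper end 7.25%). Arg1 was seen in 0.403% ± 0.044 of sorted tumor neutrophils (unthinned 1.27%). In blood neutrophils it was seen in 0 of 2899 and 0 of 4452 cells, with upper ends of the 95% Clopper-Pearson interval at 0.127% and 0.0828% for the share with a UMI at this depth. In CD45+ tumor neutrophils the Arg1 share was 6.19% and 7.98%, beside 5.77% and 6.42% in T or NK cell-like cells, 1.52% and 2.04% in B or plasma cell-like cells and 67.5% and 69.4% in phagocyte-like cells. Its interval in CD45+ neutrophils (4.24 to 8.67 and 6.08 to 10.2) overlapped that in T or NK cell-like cells (3.45 to 8.96 and 3.36 to 10.9).

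**Figure D3:**
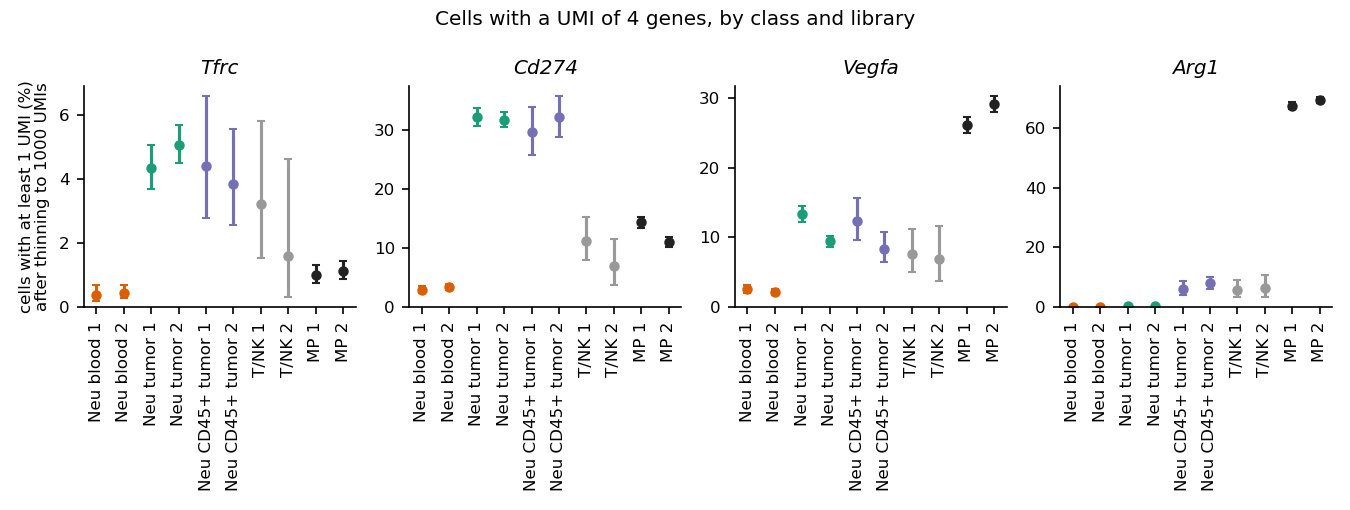
Share of cells (%) with at least 1 UMI of Tfrc, Cd274, Vegfa or Arg1 after thinning to 1000 UMIs per cell, with 95% Clopper-Pearson intervals, in neutrophil-like cells of each library and in T or NK cell-like and mononuclear phagocyte-like cells of the CD45+ tumor libraries. Tfrc lies at 4.69% ± 0.51 in sorted tumor and 0.414% ± 0.049 in blood neutrophils, and Arg1 is highest in phagocyte-like cells (67.5% and 69.4%).

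CD71 was taken from background knowledge as a marker of a tumor neutrophil subset, and Tfrc RNA stood in for it here. Neutrophil-like cells with at least 1 Tfrc UMI were compared with an equal number without, matched on total UMIs within each of the 4 tumor libraries. Median depth of positive and negative cells was 1810 and 1818, 2508 and 2535, 3903 and 3904, and 3923 and 3922 UMIs. Camera called the glycolysis and hypoxia response lists higher in Tfrc-positive cells and the granule protein and trafficking lists lower, each at an adjusted p of 0.203 with an estimated correlation. P4ha1, which encodes a collagen prolyl hydroxylase, rose by 1.90 ± 0.14 on the log2 scale (SE), to 1004 ± 332 CPM (SD, n = 4) against 262 ± 126. Hk2 rose by 1.63 ± 0.14 (1027 ± 154 against 303 ± 143) and Ero1l by 1.61 ± 0.11 (1963 ± 218 against 641 ± 113). Ldha rose by 1.19 ± 0.11 (1218 ± 293 against 531 ± 142), Slc2a1 by 1.04 ± 0.11, Vegfa by 0.93 ± 0.15 and Cd274 by 0.77 ± 0.13 (1135 ± 35.1 against 663 ± 259). Hif1a (0.16 ± 0.12, edgeR adjusted p = 0.382), Ptgs2 (0.05 ± 0.10, adjusted p = 0.768) and Arg1 (0.78 ± 0.37, adjusted p = 0.142) did not pass the test.

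The other largest rises were those of Pcid2 (1.71 ± 0.22), Ciart (1.68 ± 0.18), a repressor of the circadian clock, and Fam57b (1.595 ± 0.27). The largest falls were those of Scrg1 (−1.78 ± 0.29), the antibacterial granule gene Pglyrp1 (−1.68 ± 0.18), Fry (−1.50 ± 0.22), Hp (−1.44 ± 0.12, 268 ± 65.99 against 726 ± 146 CPM), Pi16 (−1.37 ± 0.30) and Lrg1 (−1.30 ± 0.15). Adjusted p in edgeR was 8.86e-10 for P4ha1, 3.25e-10 for Ero1l, 1.31e-08 for Hk2, 8.19e-08 for Ldha, 6.43e-07 for Slc2a1, 5.46e-05 for Vegfa, 0.000163 for Cd274 and 1.46e-08 for Hp. For the 6 largest rises and 6 largest falls, the naming rule required the same sign in all 4 libraries. Hk2 (ENSMUSG00000000628) lies on chromosome 6 at 82725025 to 82774454 on the minus strand, and P4ha1 (ENSMUSG00000019916) on chromosome 10 at 59323296 to 59373304 on the plus strand of mm10.

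Of 9 measured macrophage markers, 4 rose in Tfrc-positive cells and 0 fell (median 0.51, camera adjusted p = 0.0827). Among them were C1qb (0.57 ± 0.16) and Apoe (0.53 ± 0.13). Monocyte markers rose in 0 and fell in 2 of 4 (median −0.525, camera adjusted p = 0.726). Microglia markers rose in 1 and fell in 0 of 4 (median 0.18, camera adjusted p = 0.379). Neutrophil markers fell in 10 of 11 (median −0.64, camera adjusted p = 3.23e-13, adjusted p = 0.0172 with an estimated correlation). Beside these, glycolysis genes rose in 16 of 17 (median 0.88, camera adjusted p = 2.18e-19, adjusted p = 0.203 with an estimated correlation). Hypoxia response genes rose in 14 of 17 (median 0.96, camera adjusted p = 8.33e-21, adjusted p = 0.203 with an estimated correlation), and neither list had a fall. Lactate and pyruvate handling genes rose in 4 and fell in 1 of 7 (median 1.06, camera adjusted p = 0.0131, adjusted p = 0.204 with an estimated correlation), including Bsg, which encodes a chaperone of lactate transporters (1.07 ± 0.13). Unfolded protein response genes rose in 6 of 12 (median 0.61, camera adjusted p = 0.00441, adjusted p = 0.461 with an estimated correlation). Atf4 was at 0.87 ± 0.15.

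Granule proteins fell in 8 and rose in 1 of 11 (median −0.74, camera adjusted p = 7.71e-07, adjusted p = 0.203 with an estimated correlation). Retnlg was at −0.84 ± 0.10 (4552 ± 2014 against 7983 ± 2428 CPM). The riser was Ngp, at 1.13 ± 0.29, which stood at 674 and 9.71 CPM in neutrophil-like cells of CD45+ tumor replicates 1 and 2. Trafficking and maturation receptors fell in 9 of 14 with 0 rises (median −0.46, camera adjusted p = 6.04e-07, adjusted p = 0.203 with an estimated correlation). The chemokine receptor gene Cxcr2 was at −0.78 ± 0.12 and Selplg at −1.13 ± 0.15. Oxidative burst and redox genes fell in 7 and rose in 1 of 14 (median −0.35, camera adjusted p = 0.0218, adjusted p = 0.204 with an estimated correlation). The NADPH oxidase subunit gene Ncf1 was at −0.87 ± 0.15 and Cyba at −0.75 ± 0.13. Interferon-stimulated genes fell in 3 and rose in 1 of 23 (median −0.42, camera adjusted p = 0.0335, adjusted p = 0.461 with an estimated correlation). Isg15 was at −0.52 ± 0.14.

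The other 10 lists were not called by camera or fry. Iron handling genes rose in 4 and fell in 1 of 8. Hmox1 was at 1.33 ± 0.16 (754 ± 77.7 against 310 ± 210 CPM) and the ferritin receptor gene Ncoa4 at 0.96 ± 0.19. Immunosuppression genes rose in 5 and fell in 3 of 16. Pdcd1lg2, which encodes PD-L2, was at 0.99 ± 0.16. Among histone acylation enzymes 3 of 9 rose and 1 fell, with the deacylase genes Sirt1 (0.96 ± 0.21) and Sirt2 (0.74 ± 0.17) up and Kat2b at −0.96 ± 0.27. Chemokines and cytokines rose in 3 and fell in 3 of 16. Ccl3 was at 0.52 ± 0.09 and Il1b at −0.64 ± 0.09. Antigen presentation genes rose in 3 and fell in 1 of 6. Cd74 was at 0.55 ± 0.18 and Cd80 at −0.54 ± 0.12; Cd74 was −0.09 when positive cells needed at least 2 Tfrc UMIs. Lipid metabolism genes rose in 2 and fell in 4 of 14. Plin2 was at 0.57 ± 0.11 and Gpx4 at −0.84 ± 0.15. Immediate early and heat shock genes rose in 7 and fell in 3 of 17. Hspa1a was at 1.20 ± 0.17 and Jun at 0.89 ± 0.11, and their median was −0.01 while the mean was 0.19. Cycs (1.20 ± 0.16) was the called member of 22 oxidative phosphorylation genes, Pcna (0.76 ± 0.20) of 3 proliferation genes and Gadd45b (0.82 ± 0.11) of 14 apoptosis and survival genes.

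Across all genes, edgeR called 690 higher and 516 lower in Tfrc-positive cells among 5876 tested, from 40, 65, 438 and 770 cells per set, and DESeq2 called 411 and 286. Adjusted over the list alone, the counts were the same in 9 of the 18 lists. On that scale hypoxia response genes rose in 15, granule proteins in 2 and immunosuppression genes in 6, and interferon-stimulated genes fell in 6. Of 1546 genes called in the sorted libraries alone, 830 were measured in the CD45+ libraries and 737 (88.8%) had the same sign there. The counts were 200 and 201 of 2147 genes tested without sorted tumor replicate 1, and 218 and 199 of 2212 without sorted tumor replicate 2; fewer genes passed the expression filter there. With every sum thinned to the total of the smallest set, edgeR called 0 of 1188 genes (9 higher and 9 lower at an unadjusted p under 0.05).

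**Figure D4:**
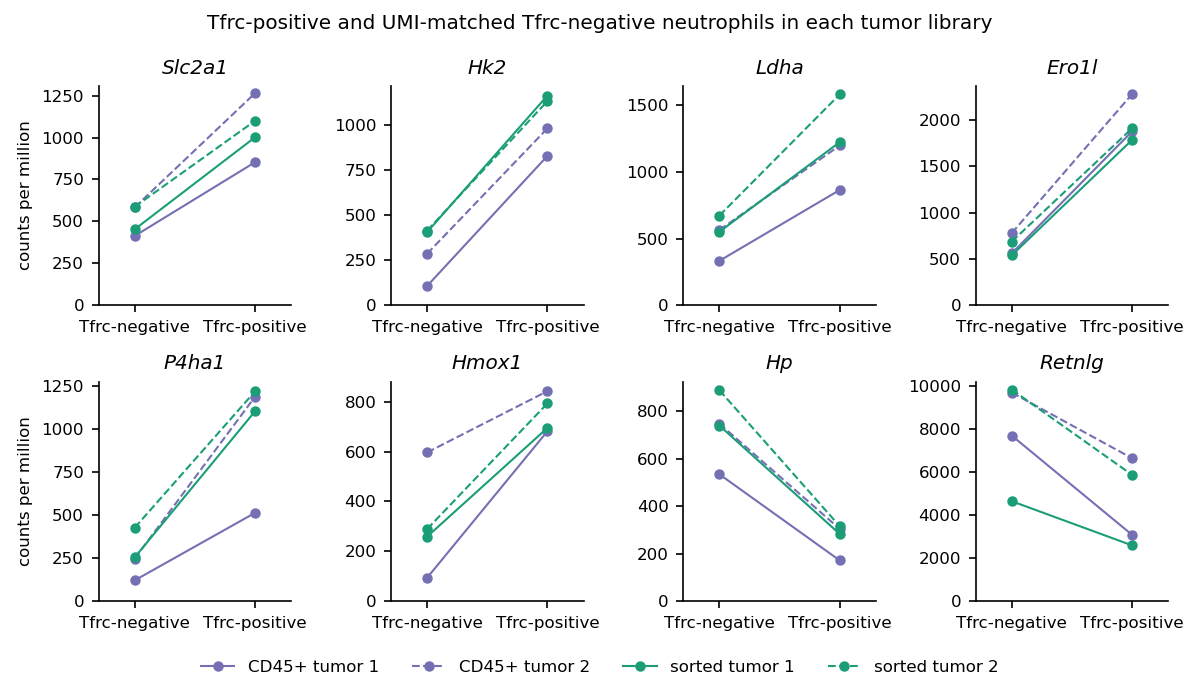
Level (CPM) of 8 genes in depth-matched Tfrc-negative and Tfrc-positive neutrophil-like cells, with a line joining both sets of each of the 4 tumor libraries. Hk2, at 1027 ± 154 against 303 ± 143 CPM (SD, n = 4), is among the genes higher in positive cells, and Hp, at 268 ± 65.99 against 726 ± 146 CPM, among those lower.

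Neutrophil-like cells of the sorted and of the CD45+ tumor libraries were compared to see how far the neutrophil profile differed between them. Phagocyte-like cells took 8.84% of the sorted and 70.8% of the CD45+ libraries. Neutrophil depth was 3754 and 3796 against 1594 and 2445 UMIs per cell. Any difference in handling also goes with the gate, so these cannot be told apart from an effect of the gate. Few genes passed the test. Arg1 was lower in the sorted cells by −3.92 ± 0.23 on the log2 scale (SE; 6.14 ± 0.52 against 92.8 ± 18.2 CPM, SD, n = 2, edgeR adjusted p = 0.00595). Fn1, a monocyte marker that encodes fibronectin, was lower by −2.57 ± 0.20 (21.8 ± 3.47 against 129.01 ± 6.65 CPM, edgeR adjusted p = 0.0173). In unscaled CPM, Arg1 was at 86.5 and 105 in CD45+ neutrophil-like cells, beside 130 and 78.1 in T or NK cell-like cells. RNA carried over from phagocytes is therefore not excluded as the source of its difference. Tfrc (0.18, edgeR adjusted p = 0.812), Hif1a (−0.25), Slc2a1 (0.20), Ldha (0.41), Vegfa (0.48), Cd274 (0.14) and Ptgs2 (0.55) did not pass. Macrophage markers had a median of −0.66 (camera adjusted p = 1.89e-10, adjusted p = 0.221 with an estimated correlation) and monocyte markers of −1.34 (camera adjusted p = 9.07e-09, adjusted p = 0.324 with an estimated correlation), with 0 and 1 members called.

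With those markers, antigen presentation genes had a median of −0.96 (camera adjusted p = 6.55e-08, adjusted p = 0.343 with an estimated correlation), and 5 of 8 were lower adjusted over the list alone. Proliferation genes had a median of −0.72 (camera adjusted p = 0.0449, adjusted p = 0.579 with an estimated correlation). Camera placed above other genes the chemokines and cytokines (median 0.38, adjusted p = 0.00121, adjusted p = 0.343 with an estimated correlation) and apoptosis and survival genes (0.30, camera adjusted p = 0.00121, adjusted p = 0.343 with an estimated correlation). Also above were immediate early and heat shock genes (0.31, camera adjusted p = 0.0041, adjusted p = 0.372 with an estimated correlation) and hypoxia response genes (0.25, camera adjusted p = 0.0178, adjusted p = 0.586 with an estimated correlation). The same held for interferon-stimulated genes (0.13, camera adjusted p = 0.0256, adjusted p = 0.471 with an estimated correlation) and glycolysis genes (0.10, camera adjusted p = 0.0441, adjusted p = 0.694 with an estimated correlation). Adjusted over the list alone, 3 apoptosis and survival genes, 2 glycolysis genes and 1 chemokine or cytokine gene were higher, and 2 proliferation genes and 1 oxidative burst gene lower. The other 10 lists were not called by camera. For immunosuppression and oxidative burst genes the median was positive (0.15 and 0.03) and the mean negative (−0.03 and −0.11). For iron handling and granule genes the median was 0.12 and 0.09 and the mean −0.04 and −0.09.

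Of 11055 genes tested, edgeR called 0 higher and 2 lower (436 and 575 at an unadjusted p under 0.05), limma-voom 0 and 4, and DESeq2 12 and 93. In CD45+ tumor replicate 1, 456 of 568 neutrophil-like cells formed a cluster of their own. The class had a median of 1594 UMIs per cell there, against 2445 in replicate 2. The counts were 8 and 37 without CD45+ tumor replicate 1 and 246 and 468 without CD45+ tumor replicate 2. Without sorted tumor replicate 1 or 2, edgeR called 0 and 0 (92 and 213, or 73 and 150, at an unadjusted p under 0.05). When genes carried over from other cells were left out, edgeR also called 0 and 0 (374 and 405 unadjusted).

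Within the CD45+ tumor libraries, neutrophil-like cells were set against mononuclear phagocyte-like cells of the same libraries, to place the neutrophil levels beside those of the main tumor leukocytes. Neutrophils had more Ptgs2 (2.98 ± 0.16 on the log2 scale, SE, n = 2 libraries), Cd274 (2.62 ± 0.16), Tfrc (2.57 ± 0.26; 59.0 and 56.4 against 8.33 and 11.1 CPM) and Slc2a1 (1.85 ± 0.15). They had less Vegfa (−1.04 ± 0.16) and Arg1 (−4.79 ± 0.19; 88.5 and 122 against 2766 and 3059 CPM). Ldha (0.11 ± 0.15) and Hif1a (0.06 ± 0.15) did not pass the test. All 13 measured trafficking and maturation receptors were higher (median 1.87, camera adjusted p = 1.02e-11, adjusted p = 0.444 with an estimated correlation). Of granule proteins 8 of 11 were higher and 1 lower (median 4.996, camera adjusted p = 4.74e-14, adjusted p = 0.444 with an estimated correlation). Oxidative phosphorylation genes were lower in 23 of 24 (median −2.03, camera adjusted p = 6.6e-09, adjusted p = 0.444 with an estimated correlation). Proliferation genes were lower in 14 of 16 (median −3.08, camera adjusted p = 0.000305, adjusted p = 0.444 with an estimated correlation) and antigen presentation genes in 8 of 10 (median −2.69, camera adjusted p = 3.38e-05, adjusted p = 0.444 with an estimated correlation).

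Chemokine and cytokine genes were higher in 11 and lower in 4 of 17 (camera adjusted p = 1.98e-06, adjusted p = 0.444 with an estimated correlation). Ccl3 was at 3.87, Cxcl3 at 3.47 and Il1b at 2.92. Immediate early and heat shock genes were higher in 13 and lower in 2 of 17 (camera adjusted p = 1.98e-06). Immunosuppression genes were higher in 9 and lower in 5 of 17 (camera adjusted p = 0.000519) and apoptosis and survival genes in 6 and 1 of 14 (camera adjusted p = 0.00231). For all 3 lists it was adjusted p = 0.444 with an estimated correlation. Interferon-stimulated genes were higher in 12 and lower in 2 of 23 (camera adjusted p = 0.00207, adjusted p = 0.634 with an estimated correlation). Glycolysis genes went both ways (camera adjusted p = 0.00641, adjusted p = 0.556 with an estimated correlation). Of 19, 9 were higher, such as Slc2a3 (5.92) and Hk2 (1.10), and 6 lower, such as Gapdh (−1.35) and Aldoc (−3.85). Hypoxia response genes were higher in 10, such as Egln3 (3.12) and Ero1l (2.34), and lower in 5 of 20 (camera adjusted p = 0.00968, adjusted p = 0.486 with an estimated correlation). Lists that camera did not call were lactate and pyruvate handling (1 higher and 5 lower of 10), iron handling (6 and 6 of 13) and histone acylation enzymes (6 and 3 of 16). The same held for the unfolded protein response (7 and 6 of 16), oxidative burst and redox (6 and 7 of 16) and lipid metabolism (7 and 8 of 17). For iron handling, histone acylation and lipid metabolism the median was negative and the direction up, and for oxidative burst the median was positive and the direction down. Of 288 list genes in no marker list, edgeR called 126 higher and 106 lower with the library as a block. This fit has 1 residual degree of freedom, so the spread came almost wholly from that pooled across genes, and single p-values are not given for this comparison. Without the block edgeR called 110 higher and 97 lower. CPM here are scaled together with phagocytes and differ from those above. Adjusted over the list alone, the counts were the same in 15 of the 18 lists.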

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

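The interaction test, its repeats without each library, the tests of depth and of phagocyte RNA and the exchanges of sets were chosen only after the result was seen.

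The difference between Tfrc-positive and Tfrc-negative neutrophil-like cells was itself tested for a difference between the sorted and the CD45+ tumor libraries. By an edgeR interaction term, 12 genes had a more positive difference in the sorted libraries and 5 a more negative one, of 5876 tested (397 at an unadjusted p under 0.05). The first set held Rgs1 (2.00 ± 0.31 on the log2 scale, SE, edgeR adjusted p = 0.000567), Gadd45g (1.78 ± 0.38, adjusted p = 0.018) and Wfdc17 (1.12 ± 0.21, adjusted p = 0.00423). It also held P2rx7, which had 0 counts in both sets of CD45+ tumor replicate 1. The second set held the monocyte marker Fn1 (−3.02 ± 0.61, edgeR adjusted p = 0.00956), the myeloid lysozyme gene Lyz2 (−1.46 ± 0.28, adjusted p = 0.00423) and Ccl9 (−1.94 ± 0.42, adjusted p = 0.018). In CD45+ tumor replicate 1 Fn1 had 40 counts in positive and 2 in negative cells, against 12 and 12 in replicate 2. Cd36 and Prok2, the other members of the second set, had 0 counts in negative cells of both CD45+ libraries. Positive cells of replicates 1 and 2 held 1 and 17 counts of Cd36 and 7 and 14 of Prok2. Both interactions therefore rest on values near the floor. Without replicate 1, Fn1, Lyz2 and Ccl9 shrank to −1.23 ± 0.64, −1.08 ± 0.31 and −1.35 ± 0.46. The counts were then 21 and 5, and 8 and 10 without CD45+ tumor replicate 2, where Rgs1 (1.74 ± 0.53, edgeR adjusted p = 0.192) and Gadd45g (1.25 ± 0.56, adjusted p = 0.534) were not called. Without sorted tumor replicate 1 or 2, edgeR called 0 of 2147 and 0 of 2212 genes (40 and 49 at an unadjusted p under 0.05). A lone library was assumed to vary like the others.

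Of glycolysis genes 16 of 17 and of hypoxia response genes 14 of 17 were called higher in Tfrc-positive cells by edgeR. Camera gave an adjusted p of 0.203 for both lists with an estimated correlation, where few residual degrees of freedom leave little power. Depth per cell as the whole cause is argued against, because the median log2 change over both lists was 0.936 with sets matched on UMIs, against 0.85 without depth matching. RNA from mononuclear phagocytes, which might enter Tfrc-positive droplets more often, stays open. Of the 30 called members, 19 stood above both Tfrc-negative cells and the pooled phagocytes in both CD45+ libraries, in sets of 40 and 65 cells. RNA at the pooled phagocyte level could not lift those above both, but RNA from a phagocyte subset with higher levels was not tested. The other members do not exclude phagocyte RNA either. Of the 8 exchanges of positive and negative sets within libraries, 1 split, the real one, called 1206 genes and the highest other called 121, while 24 splits that parted the sets of 2 libraries only called at most 216, 3 that parted none could not be fitted, and the 8 are too few for a share under 0.05. A state of hypoxic, CD71-bearing neutrophils is one of the open explanations, as a hypothesis found and tested on the same cells.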

How the results depend on the processing

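The settings without the shallow cluster and without the library block within the CD45+ libraries were chosen after seeing the data; the others here were planned. In tumor against blood neutrophils, 51 of 52 named genes kept their direction and call in every setting that gave them a value; 11 had none in at least 1 setting, as did 15 of 42 in the sorted against CD45+ and 19 of 48 in the Tfrc comparison. H2-Eb1 went from 4.49 to −0.891 (edgeR adjusted p = 0.0313) with all cells summed, where the libraries' other cells enter by construction. Calls were 1049 higher and 1068 lower among genes with a mean CPM of at least 50, which leaves fewer genes, and 2230 lower at a fold change of at least 2. All cells together gave 55 calls in the opposite direction.

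In sorted against CD45+ tumor neutrophils, higher and lower calls were 12 and 93 with DESeq2, 149 and 419 with no low-count filter, and 4 and 17 without the shallow cluster. Lower calls were 4 with limma-voom, 4 with the strict cell filter, 0 without carried-over genes and 0 with sums thinned to equal totals (edgeR, 70 higher and 243 lower at an unadjusted p under 0.05). Without each library in turn, higher calls ranged from 0 to 246 and lower calls from 0 to 468; a lone library was then assumed to vary like the other group. Of 42 named genes 22 kept their side of the threshold in every setting that gave them a value. The cause was not tested.

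In the Tfrc comparison, higher and lower calls were 411 and 286 with DESeq2, 193 and 93 at a fold change of at least 2, 0 and 0 with sums thinned to equal totals, and 13 and 20 in the CD45+ libraries alone, where sets of 40 and 65 cells limit depth. Higher calls were 411 with at least 2 Tfrc UMIs, and lower calls 328 with the strict cell filter and 871 with no depth matching. Without each library in turn, calls ranged from 200 to 886 higher and from 199 to 604 lower. Among named genes, results kept their direction and side in 867 cases, lost the call in 120, gained it in 9 and turned in 4, and 8 of 48 genes kept both in every setting that gave them a value. Selplg turned to 0.326 and Cd74 to −0.348 with equal totals (edgeR adjusted p = 0.988 for both), and Cd74 to −0.085 with at least 2 Tfrc UMIs and −0.148 in the CD45+ libraries alone. The cause was not tested.

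Whether the replicate numbers pair the samples is not known, and samples were treated as unpaired. Same-numbered libraries had correlated deviations of 0.066 (blood and sorted tumor) and 0.092 (CD45+ and sorted tumor) over only 2 pairs. With the number as a block, calls were 4267 and 4119 for tumor against blood and 8 and 14 for sorted against CD45+ libraries. Without the library block, calls were 205 and 100 in the Tfrc comparison and 110 and 97 within the CD45+ libraries.

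With an estimated correlation, camera called 0 of the 18 lists in each comparison (4, 4, 1 and 0 at an unadjusted p under 0.05). The preset value gave 12 for tumor against blood, 8 for the Tfrc sets, 8 for sorted against CD45+ and 12 against phagocytes. Fry called 13, 4, 0 and 0. The estimated setting also rests on the few residual degrees of freedom of each fit. It therefore cannot decide whether correlation between genes accounts for the calls. The tumor minus blood share of cells with a UMI was 2.28, 0.27, 5.76 and 20.8 percentage points for Tfrc, Arg1, Vegfa and Cd274 at 500 UMIs and 10.8, 1.27, 17.1 and 42.3 unthinned, against 4.27, 0.403, 8.98 and 28.8 at 1000 UMIs, since more UMIs per cell find more positive cells.

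Among cell classes of the CD45+ libraries, dendritic cell-like cells took 3.93% ± 0.442 (SD, n = 2) at a clustering resolution of 1.5 and T or NK cell-like cells 5.46% ± 2.27 at 0.5, against 9.32% and 2.98% at 1.0. Mononuclear phagocyte-like cells took 64.2% and 63.7% at 0.5 and 1.5, against 70.8%, and unnamed clusters 11.2% and 19.6%, against 7.07%. Whole clusters crossed the naming rule between resolutions. With markers of another class too close, a cluster led by dendritic cell markers (426 and 476 CD45+ cells) was unnamed at 1.5. So was one led by macrophage markers at 1.5 (84 and 859) and another at 0.5 (508 and 606). At 1.0 a cluster led by T cell markers (297 and 127) was unnamed. T or NK cell-like cells numbered 613 and 315 at 0.5, against 317 and 188 at 1.0. Other causes were not tested.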

Other observations

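The tests on Arg1 in the CD45+ tumor libraries and on the genes of CD45+ tumor replicate 1 were chosen only after the result was seen, as were the genes named in this part.

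Xist, the long noncoding RNA of the inactive X chromosome, was higher in tumor than in blood neutrophils by 2.13 ± 0.11 on the log2 scale (SE, edgeR adjusted p = 2.34e-06). It stood at 245 and 272 CPM in sorted tumor and 59.4 and 58.7 in blood neutrophils, while the nuclear RNA Malat1 was at 24169 and 24463 CPM in sorted tumor and 18809 and 19333 in blood (0.35 ± 0.17, edgeR adjusted p = 0.0976). A cluster of 220 cells, of which 208 made up 4.03% of blood replicate 2 and 6 made up 0.195% of replicate 1, was led by Retnla (8447 CPM), Lyz1 (2387 CPM), Prg4 (1796 CPM) and the lipoxygenase gene Alox15 (512 CPM), with a median of 883 UMIs per cell. Another of 112 cells, 110 of them in blood replicate 2 (2.13%), held S100a9 at 35841 CPM beside the immunoglobulin gene Igkc at 4286 CPM, with a median of 680 UMIs.

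Arg1 in neutrophil-like cells of the CD45+ tumor libraries was at 2.80% and 3.27% of that in phagocytes, below the median of 8.17% and 7.60% for macrophage markers, a mean ratio of 0.387. The lowest marker, at 1.76% (Ms4a7, 2 counts, 95% counting interval 0.213 to 6.34) and 1.97% (Mrc1, 12 counts, 1.02 to 3.45), lay below Arg1, but its interval covered it. Phagocyte RNA is consistent with the Arg1 level, and a part made by the neutrophils stays open; T or NK cell-like cells had 130 and 78.1 CPM of Arg1, beside 86.5 and 105 in neutrophils. In the sorted tumor libraries the same ratio was 0.275 (0.641% and 0.619% of the phagocyte level, against 2.92% and 1.87%), and phagocyte RNA is consistent with that level too. For a small set of neutrophils rich in Arg1, at least 10 cells with 5 or more Arg1 UMIs had been set beforehand as the bound. The count of 5 fell short of it. The bound as set named no interval, but the 95% counting interval (1.62 to 11.7) reaches it, so such a set is not excluded. Those 5 cells held 63 of the 215 Arg1 UMIs, up to 29 in a cell. Whether they were doublets with a phagocyte was not tested.

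CD45+ tumor replicate 1 had 76 genes at least 4-fold higher, at 50 CPM or more, in neutrophil-like cells than replicate 2, and free nucleic acid in the droplets of that library is a candidate source. The same genes were higher there in lymphoid cells, with a mean of 2.50 over the median log2 ratios in T or NK cell-like (2.19) and B or plasma cell-like cells (2.80), and 66 were at least 2-fold higher in T or NK cell-like cells. The UMIs of the set per cell were 21.03 in neutrophils, 25.9 in T or NK, 21.7 in B or plasma, 28.5 in dendritic and 35.4 in phagocyte-like cells of replicate 1. A state of the neutrophils alone is argued against for the set as a whole by the median ratio of 2.19 in T or NK cell-like cells. It stays open for the 10 genes under 2-fold there, among them the granule genes Ngp, Camp and Ltf, and Ngp is also the granule gene that rose in Tfrc-positive cells. These 3 granule genes were among the leading genes of cluster 8, found mainly in blood. That cluster held 3 neutrophil-like cells of CD45+ tumor replicate 1 and 0 of replicate 2. Whether the values of these genes rest on those few cells was not tested.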
